A study of Homo sapiens with 75 samples.

How the data were processed

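Regions 40 µm wide were taken with a mechanical picker from 5 µm sections of formalin-fixed, paraffin-embedded melanoma, per the labels' protocols. After proteinase K digestion, polyadenylated RNA was caught on oligo(dT) beads and amplified with the SMART-Seq v4 kit, per the labels' protocols. This kit keeps no strand information and adds no molecular barcodes, so amplified copies of 1 molecule are counted several times. Intervals and floors drawn from counts therefore cover counting error only. The deposited table holds whole-number counts per gene for 75 regions and 35096 Ensembl gene identifiers. HISAT2, Salmon, GRCh38 and hg38 are named per the submitters' processing notes, with no version or role. The step that turned reads into counts and the gene annotation are not given in the sources used here. No normalization is recorded for the deposited counts. Of the identifiers, 34939 were named from a current gene table, 151 from GENCODE 29, and 6 stayed unnamed. Positions are those of GENCODE 29 on GRCh38.

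Of all identifiers, 18523 had at least 1 count and 16573 had none. The median region had no count for 82.0% of the genes with counts, and 22 genes were counted in all regions. The floor for a class without counts was set at 3 counts over its summed total, which is 0.283 CPM for invasive tumour, 2.68 CPM for melanoma in situ and 1.08 CPM for exophytic regions. Among 2775 pairs of regions no 2 held identical counts, and the highest correlation was 0.422.

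Regions were grouped by the class in their labels. The comparisons, tests, gene lists, alternatives and the rule for named genes were written before the data were examined. Each of 8 pairs of classes was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM factors, the default filter on low counts, robust quasi-likelihood F test), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A further contrast set the difference between immune and in situ regions against that between Brisk TIL and invasive tumour regions. The 39 gene lists (525 genes) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists with at least 3 tested genes. List scores (mean log2 of CPM + 1) and list shares of counts were compared by permutation of region labels, adjusted over all lists. Depth and composition were compared by two-sided permutation of the difference in means, exact for small classes and otherwise with 100000 resamples. The contrast of differences was permuted 10000 times.

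Genes named in the text are, per comparison, the 10 with the smallest p in each direction among those called and counted in at least 0.5 of the regions of the higher class. Up to 4 members with the smallest p were added for each called list. XIST and Y-linked genes, variable segments of antibody and T cell receptor genes, genes whose presence differs between persons and unnamed features were left out. Other genes are marked as chosen after their values were seen. Alternatives were TMMwsp and DESeq2 size factors, no filter, a filter of at least 10 counts in 0.5 of the regions of a class, DESeq2 1.42.0, limma voom with quality weights, all regions in 1 fit, the number of detected genes as a covariate, a block on shared region numbers, an estimated inter-gene correlation, and leaving out single exophytic regions or regions of very low depth. Fits without the counts of COL6A3 and antibody genes or without mitochondrial counts, Fisher's exact test of detection, the fit on genes tested in both pairs of classes, the block for the contrast of differences, each block's regions without the block and thinned libraries were added after the data were seen. The shares of counts in COL6A3 and in ribosomal protein genes and the permutation test of list shares were added then too. The tests were tested on simulated data with seeded changes. A 16-fold change was recovered for 65.0% of seeded genes in Brisk TIL against invasive tumour, 35.0% at the margin, 42.0% in Brisk TIL against the margin, 0% in exophytic and 2.00% in in situ regions against invasive tumour. Within the in situ part it was recovered for 9.00%, 2.00% and 36.8%. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.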

Results

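Gene expression was measured by RNA sequencing in 75 regions picked from sections of formalin-fixed, paraffin-embedded human melanoma, each region 40 µm wide and sequenced as its own library. The regions fell into 7 histological classes. The invasive part of the disease gave 16 regions of invasive tumour, 12 of the invasive margin, 3 of exophytic melanoma (tumour growing outward from the skin surface) and 16 of Brisk TIL, the pathologist's term for a dense infiltrate of lymphocytes in a tumour. The in situ part, in which tumour cells have not left the epidermis, gave 6 regions of melanoma in situ, 14 labelled immune and 8 labelled resolved. The labels do not define the words immune and resolved any further, and they do not tie regions to persons. Some regions may therefore share a person, and p-values over regions are then too small. Regions were chosen by their histology, so immune genes in the classes labelled Brisk TIL or immune were in part selected for. Levels are given as mean CPM (counts scaled to library size) ± SD over the regions of a class, and log2 fold changes as estimates ± SE from edgeR.

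Total counts per region ran from 7855 (immune in situ region 11) to 1887657, with a median of 401240. The in situ classes held fewer counts than the invasive ones. The mean total was 186296 ± 80182 (SD, n = 6) in melanoma in situ and 661783 ± 383888 (SD, n = 16) in invasive tumour (adjusted p = 0.00257, two-sided exact permutation test). Immune in situ regions had 119211 ± 58453 counts (n = 14) and resolved in situ regions 273354 ± 220272 (n = 8). Brisk TIL, invasive margin and exophytic regions averaged 616002 ± 423915, 891827 ± 430936 and 925344 ± 553814 counts. Mitochondrially encoded transcripts took 1.94 ± 0.425% of counts in Brisk TIL, 7.53 ± 2.44% in the margin, 8.08 ± 2.54% in invasive tumour and 11.5 ± 1.76% in exophytic regions. They took 3.76 ± 2.99%, 3.87 ± 2.22% and 3.43 ± 1.23% in the in situ, immune and resolved regions. The number of genes with at least 1 count was 3047 ± 1109 in melanoma in situ and 1799 ± 559 in immune in situ regions (adjusted p = 0.0344, exact permutation test). The 10 largest genes took 17.3 ± 1.27% and 25.3 ± 6.80% of their counts (adjusted p = 0.00248). Resolved in situ regions gave 5.15 ± 1.93% of counts to ribosomal protein genes and immune in situ regions 3.19 ± 0.891% (adjusted p = 0.0344, permutation test). One gene, COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375), which encodes a chain of type VI collagen, took 1.68 ± 0.747% of counts in invasive tumour. It took 2.76 ± 1.23% in Brisk TIL (adjusted p = 0.0254, permutation test) and 6.18 ± 1.23% in melanoma in situ (adjusted p = 0.000429). The COL6A3 and ribosomal shares were chosen as measures after the data were seen.

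**Figure D1:**
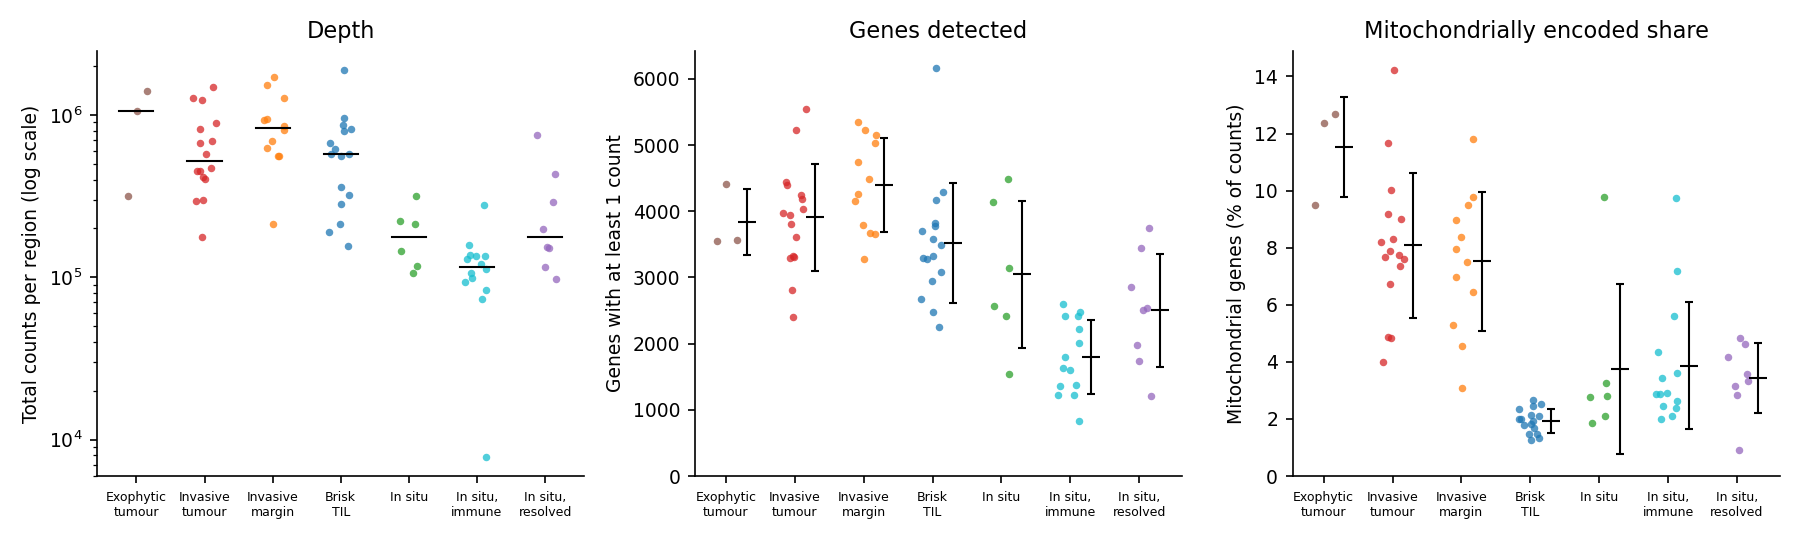
Total counts (log axis, horizontal bars at class medians), genes with at least 1 count and percent of counts from mitochondrially encoded genes, 1 point per region, by histological class; black marks with bars are mean ± SD. The 16 Brisk TIL regions lie at or below 2.65% mitochondrial counts and the 16 invasive tumour regions at or above 3.98%.

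The first comparison asked how lymphocyte-rich areas of the invasive part differ from the tumour itself. Pigment cell genes were close to absent from Brisk TIL regions. PMEL (ENSG00000185664, chromosome 12, 55954105 to 55973317), a structural protein of the melanosome, averaged 8.36 ± 32.7 CPM in 16 Brisk TIL regions and 5843 ± 1895 CPM in 16 invasive tumour regions (log2 fold change -9.19 ± 1.16, adjusted p = 1.41e-07). TYR (ENSG00000077498, chromosome 11, 89177452 to 89295759), the rate-limiting enzyme of melanin synthesis, had 0.244 ± 0.730 against 1198 ± 935 CPM, and MLANA, a melanosomal antigen, 2.21 ± 5.81 against 1688 ± 2559 CPM. SOX10 (ENSG00000100146, chromosome 22, 37970686 to 37987422), a transcription factor of the neural crest lineage, had no count in any Brisk TIL region and was at least 1635-fold lower, with 3 counts over the group as the floor (adjusted p = 5.95e-07). By the same floor SFRP1, a secreted inhibitor of Wnt signalling, was at least 4295-fold lower and DMKN, first described in the epidermis, at least 4156-fold lower. All 6 tested pigmentation genes were lower, 4 past the test over all genes and 5 when adjusted over the list alone (median log2 fold change -9.32, camera adjusted p = 3.47e-09). All 4 tested neural crest genes were lower too, 3 over all genes and 4 when adjusted over the list alone (adjusted p = 2.12e-05). Among targets of MAPK signalling, 4 were tested and lower (adjusted p = 0.0110), 1 over all genes and 2 when adjusted over the list alone. DUSP6, which dephosphorylates ERK, had 12.2 ± 39.7 against 399 ± 589.6 CPM (adjusted p = 0.0124). Brisk TIL means without the largest region were 0.192 CPM for PMEL (region 5), 0.0767 CPM for TYR (region 15), 1.08 CPM for MLANA (region 3) and 2.62 CPM for DUSP6 (region 12). The invasive tumour mean without its largest region was 1103 CPM for MLANA (region 12).

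Connective tissue and immune genes were higher in Brisk TIL. COL1A2 (ENSG00000164692, chromosome 7, 94394561 to 94431232), COL1A1 and COL3A1, the main fibrillar collagens of the dermis, averaged 2165 ± 2559, 2548 ± 3564 and 1692 ± 1435 CPM. In tumour they averaged 0.185 ± 0.740, 6.41 ± 18.7 and 3.89 ± 15.5 CPM. All 6 tested fibroblast and collagen genes were higher, 4 over all genes and 5 when adjusted over the list alone (median log2 fold change 5.76, adjusted p = 1.75e-07, and 0.00687 with an estimated correlation). LYZ (ENSG00000090382, chromosome 12, 69348341 to 69354234), the lysozyme of macrophages, was 39.8-fold higher (4015 ± 3707 against 101 ± 175 CPM, adjusted p = 0.000659). All 6 tested macrophage genes were higher, 2 over all genes and 5 when adjusted over the list alone (adjusted p = 7.75e-07). XBP1, a transcription factor of antibody-secreting cells, and PIM2, a kinase of lymphoid cells, were 62.8-fold and 52.5-fold higher. KLRD1, a receptor subunit of natural killer and cytotoxic T cells, was 34.4-fold higher (adjusted p = 0.00251). Plasma cell genes took 8.14% ± 7.20 of counts in Brisk TIL and 0.00428% ± 0.00809 in tumour (adjusted p = 4.33e-05, permutation test over 39 lists). Cytotoxic lymphocyte genes took 0.331% ± 0.347 and 0.0160% ± 0.0235 (adjusted p = 4.33e-05), and T cell genes 0.155% ± 0.142 and 0.0231% ± 0.0431 (adjusted p = 0.000195). Without tumour region 11 the tumour share of plasma cell genes was 0.00278%, and without tumour region 7 that of T cell genes 0.0148%. JCHAIN, which links antibody chains into polymers and was chosen after its values were seen, was counted in 14 of 16 Brisk TIL regions and in 0 of 16 tumour regions. Invasive tumour means without the largest region were 0 CPM for COL1A2 (region 10), 2.14 CPM for COL1A1 (region 7), 0 CPM for COL3A1 (region 10) and 0 CPM for PIM2 (region 9).

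Mitochondrially encoded genes were lower in Brisk TIL, all 12 tested members past the test (median log2 fold change -1.996, adjusted p = 3.47e-09, and 0.00696 with an estimated correlation). MT-ND2, a subunit of respiratory complex I, had 1956 ± 1538 against 10804 ± 4336 CPM. The camera test also placed ribosomal protein genes higher (median log2 fold change 0.40, adjusted p = 0.00496, 2 of 47 tested genes over all genes and 0 when adjusted over the list alone), with adjusted p = 0.169 with an estimated correlation. The list's share of counts passed (adjusted p = 0.0296) and its score did not (adjusted p = 0.261). The share of all ribosomal protein genes did not pass either (adjusted p = 0.0836 over the library measures, permutation test). Of 953 genes tested with edgeR, 25 were higher and 63 lower at an adjusted p under 0.05, 88 in all. DESeq2 called 153 genes and limma voom 249. Regions that share a person, which the labels do not show, would make these p-values too small.

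The invasive margin was compared with invasive tumour to see what sets the advancing edge apart. Genes induced by interferon gamma stood higher at the margin as a group, while the pigment gene PMEL remained high. PMEL, a gene chosen after its values were seen, had 4437 ± 1495 CPM in 12 margin regions and 5843 ± 1895 CPM in 16 tumour regions. Of 11 tested pigmentation genes only 2 were higher at the margin (median log2 fold change -0.99, camera adjusted p = 0.0663). Of 10 tested neural crest genes 4 were higher (median -0.51, adjusted p = 0.0663). Neither list passed. GBP2, an interferon-induced GTPase, had 884 ± 910.5 against 64.9 ± 114 CPM, and IDO1, a tryptophan-degrading enzyme, 346 ± 407 against 36.5 ± 60.1 CPM. CXCL9, a chemokine that attracts T cells, had 1069 ± 1234 against 106 ± 328 CPM, and IRF1, a transcription factor of the interferon response, 534 ± 640.1 against 70.1 ± 173 CPM. IDO1, CXCL9 and IRF1 were counted in all 12 margin regions. None of these genes passed the test on its own over all genes; the smallest adjusted p among them was 0.526. As lists, all 11 tested interferon gamma genes were higher (median log2 fold change 2.77, camera adjusted p = 1.16e-13, and 0.00113 with an estimated correlation), 5 of them when adjusted over the list alone. All 3 tested macrophage genes were higher (median 2.91, adjusted p = 1.53e-05, and 0.00940 with an estimated correlation), 2 of them when adjusted over the list alone. Interferon gamma genes took 0.967% ± 0.640 of counts at the margin and 0.231% ± 0.242 in tumour (adjusted p = 0.00117, permutation test), and macrophage genes 0.238% ± 0.268 and 0.0601% ± 0.0727 (adjusted p = 0.00887). T cell genes took 0.0181% and 0.0231%, and cytotoxic lymphocyte genes 0.0491% and 0.0160%. Neither of these lymphocyte lists passed by share. Lymphoid chemokines took 0.199% ± 0.162 and 0.0454% ± 0.0635 (adjusted p = 0.00887), and genes of MHC class II presentation, mostly CD74 (named after its values were seen), 0.796% ± 0.190 and 0.352% ± 0.294 (adjusted p = 0.00312). The class II chains themselves, also named after their values were seen, were low. HLA-DRA averaged 11.6 ± 34.9 CPM at the margin and 18.4 ± 51.5 CPM in tumour, HLA-DPA1 124 ± 205 and 78.8 ± 238 CPM, HLA-DRB1 0.0544 ± 0.189 and 0 CPM, and HLA-DQB1 0 and 0 CPM. The score of that list did not pass (adjusted p = 0.272), and how reads of these variable genes were counted is not given in the sources used here. edgeR called 0 of 1641 genes, with 84 at an unadjusted p under 0.05. DESeq2 called 11, with no adjusted p for 923 of the 1641 genes, limma voom 15 and Fisher's exact test of detection 0. With at least 10 counts in 0.5 of the regions of a class edgeR called 26, 22 higher and 4 lower. With no filter it called 4094, 1948 higher and 2146 lower. As the labels do not tie regions to persons, p-values over regions that share one are too small. Invasive margin means without the largest region were 1.62 CPM for HLA-DRA (region 8), 80.0 CPM for HLA-DPA1 (region 4) and 0 CPM for HLA-DRB1 (region 9). Invasive tumour means without the largest region were 25.5 CPM for CXCL9 (region 11), 29.3 CPM for IRF1 (region 9), 7.91 CPM for HLA-DRA (region 8) and 20.7 CPM for HLA-DPA1 (region 11).

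Brisk TIL regions were next set against the invasive margin, where pigment, macrophage and interferon gamma genes are all present. Antibody and matrix genes were higher in Brisk TIL, and pigment and interferon gamma genes lower. JCHAIN (ENSG00000132465, chromosome 4, 70655541 to 70681817) averaged 2595 ± 3269 CPM in Brisk TIL and 0.199 ± 0.497 CPM at the margin (log2 fold change 12.72 ± 1.46, adjusted p = 3.19e-08), and IGLC1, an antibody light chain gene, 5651 ± 7929 and 15.8 ± 54.9 CPM (adjusted p = 0.0160). IGLC2 and IGLC3, whose near-identical sequences make their counts uncertain, had 38894 ± 39181 and 10582 ± 10220.5 CPM in Brisk TIL. All 6 tested plasma cell genes were higher, 2 over all genes and 5 when adjusted over the list alone (median log2 fold change 5.39, camera adjusted p = 3.95e-10, and 0.0106 with an estimated correlation). The list took 8.14% ± 7.20 against 0.141% ± 0.472 of counts (adjusted p = 0.00312, permutation test). Margin region 5 alone held 1.64%, and without it the margin share was 0.00485%. DCN, a proteoglycan of the dermis, had 905 ± 1268 against 2.96 ± 7.08 CPM (adjusted p = 0.000233), and 10 of 11 tested fibroblast genes were higher, 2 over all genes and 6 when adjusted over the list alone (adjusted p = 3.95e-10). CXCR4, a chemokine receptor of lymphocytes, was 42.1-fold higher and LYZ 5.29-fold higher. All 5 tested cytotoxic lymphocyte genes were higher, 2 when adjusted over the list alone (adjusted p = 0.00255). CD8A had 347 ± 461 against 59.7 ± 92.5 CPM, with an adjusted p of 0.459 over all genes. The macrophage list was called higher (9 of 10 tested genes, 1 passing over all genes and 1 over the list alone, adjusted p = 0.00227), with adjusted p = 0.115 with an estimated correlation. It passed by share of counts (adjusted p = 0.00485) and by score (adjusted p = 0.00378). Invasive margin means without the largest region were 0.0715 CPM for JCHAIN (region 3), 0 CPM for IGLC1 (region 5), 1.27 CPM for DCN (region 2), 0 CPM for CXCR4 (region 12), 475 CPM for LYZ (region 12) and 39.4 CPM for CD8A (region 6).

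WARS1, the interferon-induced tryptophanyl-tRNA synthetase, was 18.2-fold lower in Brisk TIL than at the margin (48.0 ± 75.9 against 872 ± 529.5 CPM, adjusted p = 0.00229). Of 11 tested interferon gamma genes, 10 were lower, 1 over all genes and 3 when adjusted over the list alone (median log2 fold change -1.47, adjusted p = 0.00227), and the list took 0.447% ± 0.223 against 0.967% ± 0.640 of counts (adjusted p = 0.00312). PMEL, TYR and CLN8, an endoplasmic reticulum protein of lipid metabolism, were lower in Brisk TIL by 9.16 ± 1.22, 11.39 ± 1.10 and 9.78 ± 1.18 on the log2 scale. All 4 tested pigmentation genes were lower, 3 over all genes (adjusted p = 1.24e-08), as were all 11 tested mitochondrially encoded genes, each past the test (median log2 fold change -2.17, adjusted p = 2.89e-09). Glycolysis and hypoxia genes were called lower (7 of 7 tested, 0 over all genes, 1 over the list alone, adjusted p = 0.0298; adjusted p = 0.0639 with an estimated correlation), with NDRG1 at 12.4 ± 18.3 against 161 ± 197 CPM. Ribosomal protein genes were called higher (31 of 47 tested, 0 past either test of single genes, adjusted p = 0.00626; adjusted p = 0.178 with an estimated correlation). By permutation the hypoxia list passed by score (adjusted p = 0.000111) and share (adjusted p = 0.0190), and the ribosomal list by share (adjusted p = 0.0273) but not by score (adjusted p = 0.188). The share of all ribosomal protein genes did not pass (adjusted p = 0.0836 over the library measures, permutation test). edgeR called 53 of 1344 genes, 11 higher and 42 lower. DESeq2 called 102, limma voom 224, and edgeR 32 once mitochondrial counts were left out. P-values here too are too small where regions share a person.

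**Figure D2:**
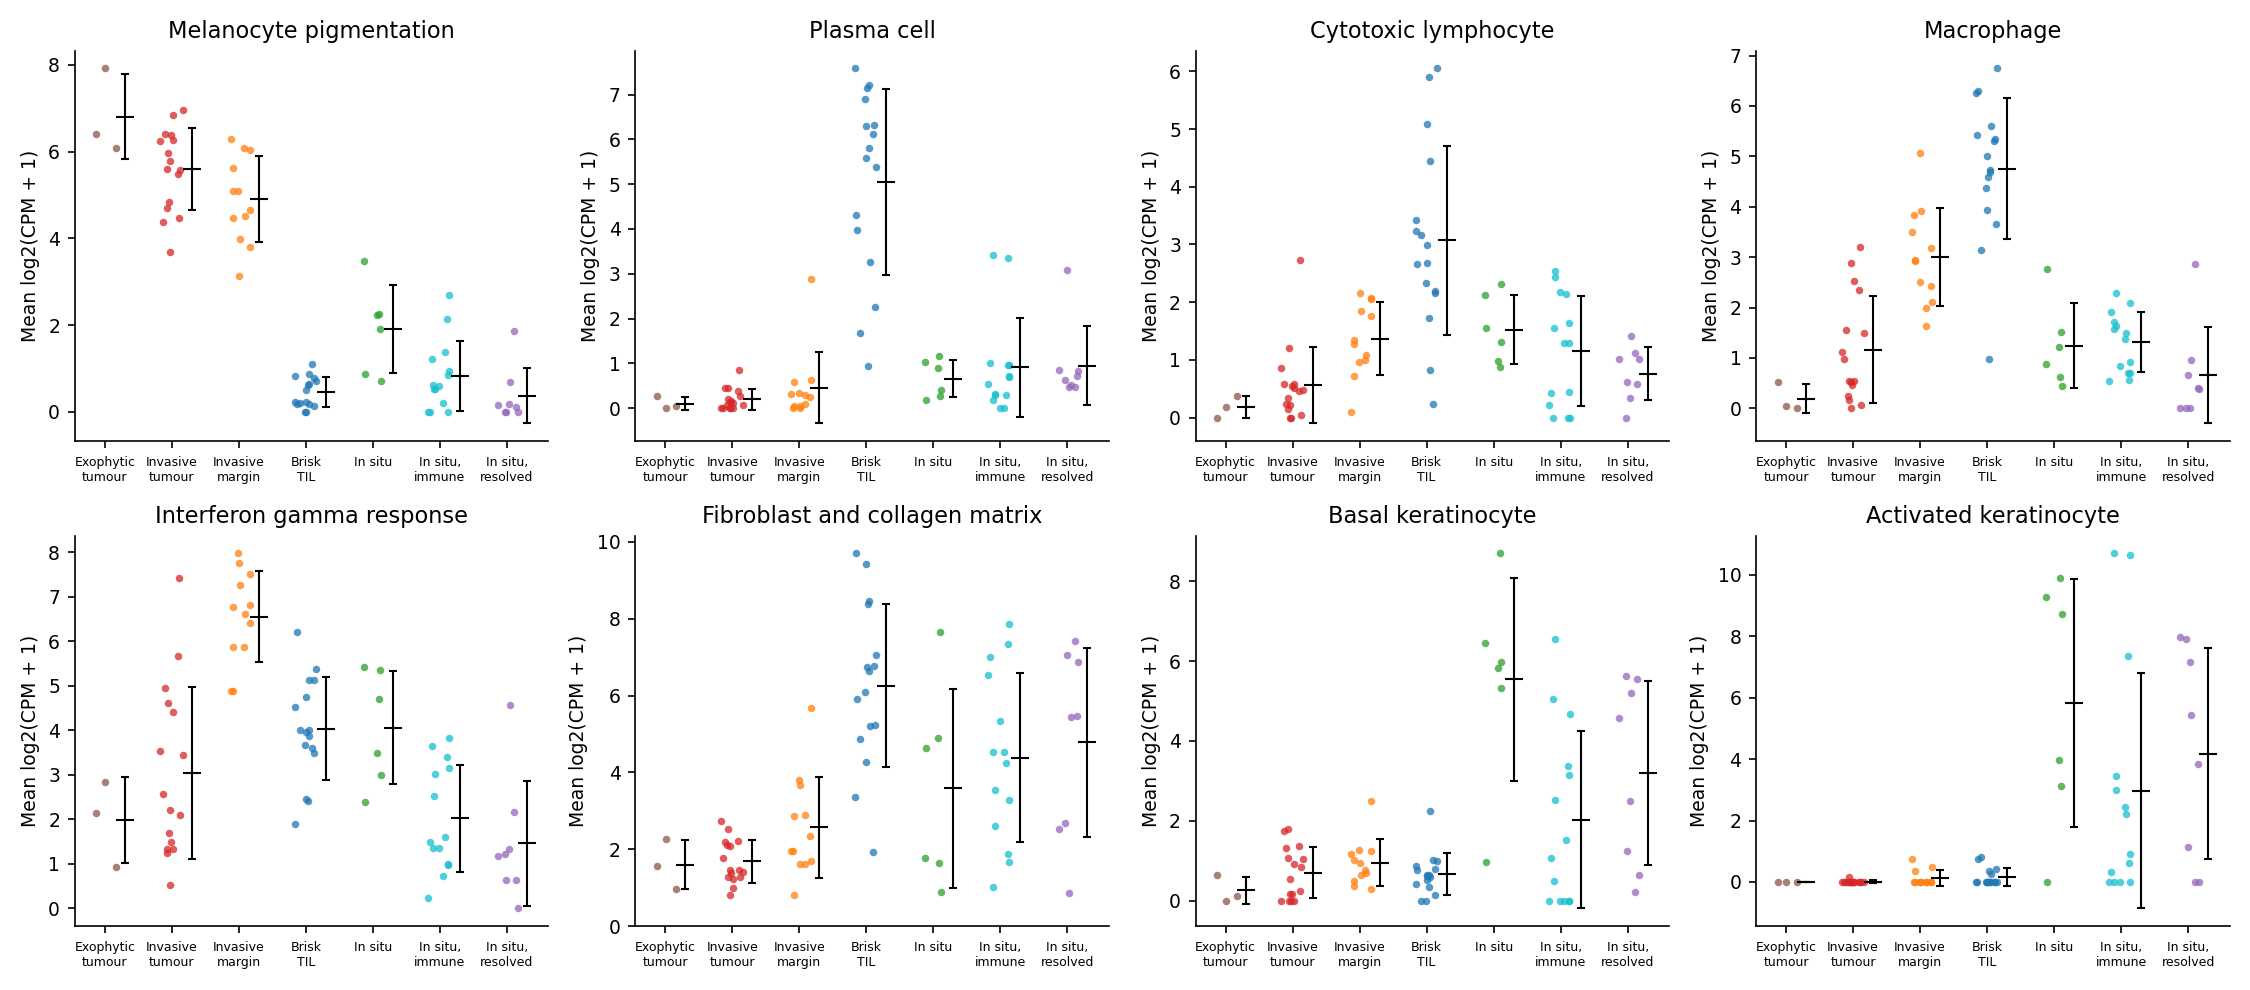
Mean log2(CPM + 1) over the genes of 8 lists, 1 point per region, by histological class; black marks with bars are mean ± SD. Pigmentation scores average 5.60 in invasive tumour and 0.45 in Brisk TIL, interferon gamma scores are highest at the invasive margin (6.55), and keratinocyte scores are high only in some of the in situ regions.

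Exophytic tumour was compared with invasive tumour on 3 and 16 regions. Pigment genes were high in both, with TYR at 3426 ± 2017 CPM in exophytic and 1198 ± 935 CPM in invasive regions. IFI6, an interferon-induced mitochondrial protein, had 1293 ± 251 and 749 ± 457 CPM. CD74, the invariant chain of MHC class II, had 373 ± 308 and 3107 ± 2531 CPM. These 3 genes were chosen after their values were seen, and none passed the test. edgeR called 5 of 6218 genes, all higher in exophytic regions, and in each most of the counts came from 1 region. For STXBP4, a syntaxin-binding protein, that region held 99.8% of the summed CPM of the class (adjusted p = 6.02e-18). The others were LEPROT, encoded at the leptin receptor locus (99.9%), MTERF3, a mitochondrial transcription factor (77.2%), ZNF141, a zinc finger protein (99.95%), and DYNC1LI2, a dynein subunit (97.3%). Without exophytic region 1 the log2 fold change of LEPROT went from 7.40 to -2.93. Without region 2 that of ZNF141 went from 6.86 to -4.18, and STXBP4, MTERF3 and DYNC1LI2 no longer passed. STXBP4 went from 12.46 to 4.17 (adjusted p = 0.362) and DYNC1LI2 from 6.31 to 1.71 (adjusted p = 0.782), while MTERF3 went from 10.66 to 8.96 (adjusted p = 0.144) and so kept a large fold change. The count of called genes was 10, 9 and 14 without regions 1, 2 and 3. None of 21 tested lists passed the camera test. Genes seeded with a 16-fold change into simulated counts of this design were recovered in 0% of cases. DESeq2 called 186 genes, 4 higher and 182 lower in exophytic regions, a balance opposite to that of edgeR, and 1 of the 5 edgeR genes was among them. DESeq2 gave no adjusted p for 3402 of the 6218 genes, so the 2 tests did not judge the same set of genes. limma voom called 56, 44 higher and 12 lower, and Fisher's exact test of detection 0. P-values over regions that share a person are too small.

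Melanoma in situ was compared with invasive tumour to see what separates the confined from the invasive lesion. Pigment cell genes were lower in the 6 in situ regions than in the 16 invasive regions. PMEL averaged 131 ± 186 against 5843 ± 1895 CPM (log2 fold change -5.76 ± 1.02, adjusted p = 0.000476). TYR had 5.52 ± 13.5 against 1198 ± 935 CPM, MLANA 54.0 ± 104 against 1688 ± 2559 CPM, and QPCT, a glutaminyl cyclase, 0.524 ± 1.28 against 647 ± 563 CPM. SOX10 had no count in any in situ region and was at least 185-fold lower (adjusted p = 0.00910). Of 14 tested pigmentation genes, 14 were lower, 4 over all genes and 8 when adjusted over the list alone (median log2 fold change -5.47, camera adjusted p = 1.37e-05). The list took 0.161% ± 0.136 against 1.24% ± 0.480 of counts (adjusted p = 0.000174, exact permutation test). Of 10 tested neural crest genes, 9 were lower, 4 over all genes and 7 when adjusted over the list alone (adjusted p = 8.08e-08). ASAH1, a lysosomal ceramidase, CLN8 and SERPINE2, a secreted protease inhibitor, were lower as well, at 3.09 ± 4.78, 2.33 ± 3.94 and 51.5 ± 80.4 CPM in situ against 1462 ± 773, 1277 ± 601 and 3605 ± 2194 CPM. RHOBTB3 and APOD, a lipid carrier, had no count in situ and were at least 314-fold and 236-fold lower. Lists of lysosome and ferritin genes (12 of 12 tested lower, 1 over all genes and 2 over the list alone, adjusted p = 0.00119), invasion genes (6 of 6, 1 and 3, adjusted p = 0.0123) and MAPK targets (5 of 6, 2 and 3, adjusted p = 0.0123) were lower. FTH1, the ferritin heavy chain, had 1270.1 ± 967 against 6513 ± 2028 CPM and TGFBI, a matrix protein, 45.7 ± 80.9 against 1006 ± 1134 CPM. The invasive tumour mean without its largest region was 1103 CPM for MLANA (region 12). Melanoma in situ means without the largest region were 57.2 CPM for PMEL (region 2), 0 CPM for TYR (region 1), 12.0 CPM for MLANA (region 3), 0 CPM for QPCT (region 5), 1.81 CPM for ASAH1 (region 4), 0.904 CPM for CLN8 (region 4), 27.7 CPM for SERPINE2 (region 4) and 15.1 CPM for TGFBI (region 4).

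Genes of the basal epidermis were higher in situ. KRT5 and KRT14, the keratin pair of basal keratinocytes, were counted in 5 of 6 in situ regions at 6554 ± 3479 and 4900.3 ± 3771 CPM. Neither had a count in any of the 16 invasive tumour regions, which by the floor of 3 counts allows up to 0.283 CPM over the group. Both were chosen after their values were seen, and the filter on low counts left them out of the gene test. KRT15, a keratin of the same layer, had 251 ± 397 against 4.54 ± 14.3 CPM (adjusted p = 0.0483), with 69.7% of its summed CPM in 1 region. All 3 tested basal keratinocyte genes were higher, 1 over all genes and over the list alone (adjusted p = 0.000887). The list took 1.40% ± 0.765 of counts against 0.0155% ± 0.0248 (adjusted p = 0.000627, exact permutation test). JUNB, an immediate early transcription factor, had 615 ± 459 CPM in 6 of 6 in situ regions against 8.37 ± 33.5 CPM (adjusted p = 0.0465). All 5 tested immediate early and heat shock genes were higher, 1 over all genes and 2 over the list alone (adjusted p = 4.27e-07). DSC3, a desmosomal cadherin of keratinocytes, was 111-fold higher in 5 of 6 regions, with 30.6% in its largest region, and COL6A3 was 3.67-fold higher. For the other genes among the 10 with the smallest p, a single region held most of the counts: ZBTB25 99.2%, KLRD1 96.9%, PERP, a desmosomal protein, 68.1%, ZNF850 72.1%, SYTL1 81.5%, PEX26 77.4%, FAM98C 96.1% and SLC35A3 99.6%. Invasive tumour means without the largest region were 1.04 CPM for KRT15 (region 12), 0 CPM for JUNB (region 11) and 0.902 CPM for DSC3 (region 9). The melanoma in situ mean without its largest region was 91.4 CPM for KRT15 (region 5).

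For 3 further lists the camera call against invasive tumour was lost with an estimated correlation. Mitochondrially encoded genes were lower (13 of 13 tested, 1 over all genes and 5 over the list alone, adjusted p = 0.0123; adjusted p = 0.396 with an estimated correlation), MT-ND2 at 3380.1 ± 4036 against 10804 ± 4336 CPM. Their share of counts passed, at 3.76 ± 2.99% against 8.08 ± 2.54% (adjusted p = 0.0229 over the library measures, exact permutation test), and was 2.55% without in situ region 4. Nuclear genes of oxidative phosphorylation were lower (11 of 15, 1 over all genes and over the list alone, adjusted p = 0.0375; adjusted p = 0.250 with an estimated correlation). Their score passed (adjusted p = 0.00279) and their share of counts did not (adjusted p = 0.625). The interferon gamma list was called higher (adjusted p = 0.0193; adjusted p = 0.267 with an estimated correlation) although its median log2 fold change was -0.17 and its mean 0.70, with 4 of 10 tested genes above 0. That list took 0.871% ± 0.976 of counts in situ and 0.231% ± 0.242 in tumour (adjusted p = 0.0262), and 0.477% in situ without region 5 (unadjusted p = 0.0485), but did not pass by score (adjusted p = 0.351). IRF1 had 1166 ± 1257 against 70.1 ± 173 CPM. edgeR called 171 of 2768 genes, 17 higher and 154 lower, and 9.94% of the called genes were higher. The share was 40.0% of 55 genes with TMMwsp factors and 21.5% of 65 genes with DESeq2 size factors. The median log2 fold change of all tested genes was -1.22. Fisher's exact test of detection called 5 genes, all lower in situ, and p-values over regions that share a person are too small. The invasive tumour mean without its largest region was 29.3 CPM for IRF1 (region 9). The melanoma in situ mean without its largest region was 1750.2 CPM for MT-ND2 (region 4).

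Within the in situ part, regions labelled immune were compared with melanoma in situ on 14 and 6 regions. Mean scores of 6 of 39 lists were lower in immune in situ regions, but no list differed in its share of counts by the test. JUNB had 22.2 ± 67.5 CPM in immune regions and 615 ± 459 CPM in situ, and IRF1, chosen after its values were seen, 251 ± 378 and 1166 ± 1257 CPM. Mean list scores, as log2(CPM + 1), were 1.49 ± 1.00 against 3.98 ± 1.63 for immediate early and heat shock genes (adjusted p = 0.0131, exact permutation test) and 2.02 ± 1.20 against 4.06 ± 1.28 for interferon gamma genes (adjusted p = 0.0322). They were 2.03 ± 2.22 against 5.54 ± 2.53 for basal keratinocyte genes (adjusted p = 0.0451) and 0.09 ± 0.18 against 0.62 ± 0.20 for dendritic and Langerhans cell genes (adjusted p = 0.00704). The number of genes detected was lower in immune regions too, and a score falls when fewer of its genes are counted. As shares of counts, 0 of 39 lists passed, with adjusted p = 0.641 for immediate early, 0.602 for interferon gamma and basal keratinocyte and 0.373 for dendritic cell genes. Camera gave adjusted p = 0.0528 for the interferon gamma and 0.0678 for the basal keratinocyte list. Camera called complement genes (3 of 4 tested above 0, adjusted p = 0.0293), fibroblast genes (6 of 9, adjusted p = 0.00676) and lysosome genes (7 of 8, adjusted p = 0.0256) higher and immediate early genes (3 of 4 below 0, adjusted p = 0.0327) lower. Over the list alone, 1 immediate early gene passed and no member of the other lists. None of these 4 calls held with an estimated correlation. The complement and fibroblast lists had adjusted p = 0.219 with an estimated correlation, and the lysosome and immediate early lists adjusted p = 0.203 with an estimated correlation. C1S, a complement protease, had 394 ± 394 against 58.5 ± 138 CPM, and CTSB, a lysosomal protease, 988 ± 954 against 216 ± 227 CPM. DCN had 2789.7 ± 7014 against 317 ± 458 CPM. edgeR called 0 of 589 genes, with 26 at an unadjusted p under 0.05. DESeq2 called 4, limma voom 6 and Fisher's exact test 0. Regions that share a person make the p-values too small. Melanoma in situ means without the largest region were 2.29 CPM for C1S (region 5) and 180.4 CPM for DCN (region 6). Immune in situ means without the largest region were 4.34 CPM for JUNB (region 11) and 981 CPM for DCN (region 16). Immune region 11 was the library with only 7855 counts.

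Regions labelled resolved were compared with melanoma in situ on 8 and 6 regions. Interferon gamma genes took a smaller share of counts in them, but no list passed by its score. WARS1 averaged 36.3 ± 52.5 CPM in 8 resolved regions and 1122 ± 1893 CPM in 6 in situ regions, and IRF1 58.8 ± 123 and 1166 ± 1257 CPM. GBP1, an interferon-induced GTPase, had 65.2 ± 114 and 489 ± 585 CPM, and 71.5% of the in situ WARS1 signal lay in 1 region. All 4 tested interferon gamma genes were lower, 2 of them when adjusted over the list alone (median log2 fold change -3.71, camera adjusted p = 0.00192; adjusted p = 0.0234 with an estimated correlation). The list took 0.0787% ± 0.108 against 0.871% ± 0.976 of counts (adjusted p = 0.0260, exact permutation test), and genes of MHC class I presentation 0.119% ± 0.0930 against 0.412% ± 0.154 (adjusted p = 0.0260). In situ region 5 held 2.84% for the interferon gamma list, and without it the in situ share was 0.477%. Without resolved region 21 the resolved share was 0.0477%. Interferon gamma scores were 1.47 ± 1.40 against 4.06 ± 1.28 (adjusted p = 0.0866), the MHC class I score had adjusted p = 0.0866, and 0 of 39 lists passed by score. Ribosomal protein genes were higher in resolved than in situ regions (35 of 46 tested, 0 past either test of single genes, adjusted p = 0.00696; adjusted p = 0.533 with an estimated correlation), RPS20 at 865 ± 681 against 131 ± 186 CPM. Against immune in situ regions, ribosomal protein genes were again higher (39 of 43 tested, 0 past either test of single genes, adjusted p = 0.000121) and lysosome genes lower (4 of 6, 0 past either test, adjusted p = 0.0304), both with adjusted p = 0.130 with an estimated correlation. RPS2 had 986 ± 934 against 149 ± 216 CPM and FTH1 440 ± 363 against 1836 ± 3028 CPM. PSAP, a precursor of lysosomal activators, had 291 ± 624 against 1226 ± 2433 CPM. Counts of ribosomal protein genes can be shared with their many pseudogenes. Dendritic and Langerhans cell genes took 0.0154% ± 0.0138 against 0.00134% ± 0.00319 of counts (adjusted p = 0.0359, permutation test), the latter 0.000614% without immune region 16. No other list, the ribosomal list included, passed by its share of counts against immune regions. edgeR called 0 of 504 genes against in situ regions, with 20 at an unadjusted p under 0.05, DESeq2 1, limma voom 1 and Fisher's exact test 0. With at least 10 counts in 0.5 of the regions of a class edgeR called 70, 9 higher and 61 lower, and with no filter 0. Against immune regions edgeR called 0 of 349 genes, with 18 at an unadjusted p under 0.05, DESeq2 0, limma voom 2 and Fisher's exact test 0. The same stricter filter gave 10, all higher, and no filter 4769, 2510 higher and 2259 lower. Here too p-values are too small where regions share a person. Melanoma in situ means without the largest region were 384 CPM for WARS1 (region 6), 306 CPM for GBP1 (region 3) and 69.4 CPM for RPS20 (region 1). Immune in situ means without the largest region were 1086 CPM for FTH1 (region 11) and 693 CPM for PSAP (region 19). Immune region 11 was the library with only 7855 counts. Resolved in situ means without the largest region were 20.9 CPM for WARS1 (region 21), 16.2 CPM for IRF1 (region 28), 30.7 CPM for GBP1 (region 27) and 73.4 CPM for PSAP (region 25).

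The last comparison set the difference of immune minus in situ regions against that of Brisk TIL minus invasive tumour regions. It asked whether regions labelled for immune cells differ from the others alike in both parts of the disease. Immune in situ is the label's word, and those regions were not shown to be rich in immune transcripts. The plasma cell score differed by 4.85 in the invasive and 0.25 in the in situ part. The macrophage score differed by 3.59 in the invasive and 0.07 in the in situ part, and the cytotoxic lymphocyte score by 2.51 in the invasive and -0.37 in the in situ part. Each had an adjusted p of 0.000355 for the difference of differences (permutation test with 10000 resamples). The pigmentation score differed by -5.14 in the invasive and -1.08 in the in situ part and the interferon gamma score by 1.00 in the invasive and -2.04 in the in situ part (adjusted p = 0.000355 for each). Scores cannot fall below 0, and the pigmentation score averaged 1.91 in melanoma in situ. A difference of -5.14 was not possible there, so the pigmentation result, by score or share, was in part fixed in advance. Basal keratinocyte scores reached at most 1.79 in invasive tumour, and immediate early scores at most 2.40 outside region 11. Mean falls as large as in the in situ part were not possible there, so these results were in part fixed in advance too. By shares of counts the plasma cell, macrophage and pigmentation lists passed (adjusted p = 0.000557 for each), and the cytotoxic lymphocyte and interferon gamma lists did not (adjusted p = 0.290 and 0.0723). Of 39 lists, 19 passed by score and 11 by share. Fewer genes were detected in immune than in in situ regions (means of 1799 and 3047), and a score falls when fewer of its genes are counted. Of the single genes, PMEL was lower in Brisk TIL than in invasive tumour, but had 217 ± 668 CPM in immune in situ and 131 ± 186 CPM in in situ regions (log2 difference of differences 9.73 ± 2.65, adjusted p = 0.00735). COL1A2 had 2310.3 ± 3031 CPM in immune in situ and 1143 ± 1666 CPM in in situ regions (difference of differences -11.48 ± 2.01, adjusted p = 1.20e-05), and LYZ 285 ± 462 and 422 ± 658 CPM (adjusted p = 0.0153). On the genes tested in both pairs of classes their adjusted p was 0.0101 for PMEL, 5.58e-07 for COL1A2 and 0.0101 for LYZ. COL1A2 averaged 0.185 CPM in invasive tumour and 2165 CPM in Brisk TIL. From 1143 CPM an equal log2 rise would exceed all counts of a library, so the COL1A2 result was in part fixed in advance. The order of the 2 in situ means turned for PMEL without immune region 12 and for LYZ without in situ region 4. IGKC, the kappa light chain of antibodies, averaged 15733 ± 21282 CPM in Brisk TIL and 407 ± 856 CPM in immune in situ regions. Its adjusted p of 0.000414 comes from the contrast over all tested genes only, as it was not tested within either pair of classes, and that contrast called a median of 275 genes on shuffled classes. Melanoma in situ means without the largest region were 57.2 CPM for PMEL (region 2), 680.4 CPM for COL1A2 (region 6) and 172 CPM for LYZ (region 4). Immune in situ means without the largest region were 39.5 CPM for PMEL (region 12), 182 CPM for LYZ (region 17) and 239 CPM for IGKC (region 18).

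By camera, 14 of 29 tested lists differed between the 2 parts, 4 with a difference higher in situ and 10 with one lower in situ. Pigmentation genes lay above 0 in 12 of 13 cases, 7 over all genes and 7 over the list alone (adjusted p = 9.79e-11). Neural crest genes lay above 0 in 9 of 10 cases, 2 over all genes and 2 over the list alone (adjusted p = 1.46e-08). MAPK target genes lay above 0 in 5 of 7 cases, 0 over all genes and 1 over the list alone (adjusted p = 0.00455), while 1 passed over all genes and 1 over the list alone in the other direction. Mitochondrially encoded genes lay above 0 in 12 of 13 cases, 0 over all genes and 0 over the list alone (adjusted p = 6.23e-05; adjusted p = 0.0758 with an estimated correlation). Plasma cell genes lay below 0 in 11 of 11 cases, 4 over all genes and 5 over the list alone (adjusted p = 1.09e-06). Macrophage genes lay below 0 in 10 of 13 cases, 6 over all genes and 6 over the list alone (adjusted p = 5.86e-06), while 1 passed over all genes and 2 over the list alone in the other direction. Cytotoxic lymphocyte genes lay below 0 in 10 of 11 cases, 4 over all genes and 4 over the list alone (adjusted p = 0.000110), while 0 passed over all genes and 1 over the list alone in the other direction. Lymphoid chemokine genes lay below 0 in 5 of 8 cases, 2 over all genes and 4 over the list alone (adjusted p = 0.000291), while 0 passed over all genes and 1 over the list alone in the other direction. Fibroblast and collagen genes lay below 0 in 14 of 16 cases, 9 over all genes and 9 over the list alone (adjusted p = 2.44e-09). Immediate early and heat shock genes lay below 0 in 5 of 8 cases, 1 over all genes and 1 over the list alone (adjusted p = 0.000716). Interferon gamma genes lay below 0 in 12 of 15 cases, 3 over all genes and 5 over the list alone (adjusted p = 0.00113; adjusted p = 0.0758 with an estimated correlation), while 1 passed over all genes and 1 over the list alone in the other direction. Ribosomal protein genes lay below 0 in 35 of 48 cases, 0 over all genes and 0 over the list alone (adjusted p = 0.0114; adjusted p = 0.365 with an estimated correlation). Basal keratinocyte genes lay below 0 in 6 of 7 cases, 1 over all genes and 1 over the list alone (adjusted p = 0.0115; adjusted p = 0.166 with an estimated correlation). Activated keratinocyte genes lay below 0 in 6 of 8 cases, 2 over all genes and 2 over the list alone (adjusted p = 0.0357; adjusted p = 0.469 with an estimated correlation). Room for change differed between the parts here too. The collagen gene COL1A2 was already high in melanoma in situ, while keratinocyte and immediate early scores were already low in invasive tumour.

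Of 5799 tested genes edgeR called 703, 212 higher and 491 lower. On the 394 genes that passed the count filter in both pairs of classes it called 17, 10 higher and 7 lower. Among them were the melanosome gene PMEL, the collagen gene COL1A2, the Wnt inhibitor SFRP1, the lysozyme gene LYZ and the mitochondrial gene MT-ND2. DESeq2 called 519 of all tested genes, 245 higher and 274 lower, limma voom 237, 147 higher and 90 lower, and edgeR with the number of detected genes as a covariate 503, 241 higher and 262 lower. DESeq2 gave no adjusted p for 1823 of the 5799 genes. Most calls were lower in edgeR, while most were higher in limma voom. With a block on region numbers present in at least 2 of the 4 classes edgeR called 31, and the same regions without the block gave 664. Region numbers are not said to pair regions, so this block does not test for shared persons. Regions that share a person make all these p-values too small.

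**Figure D3:**
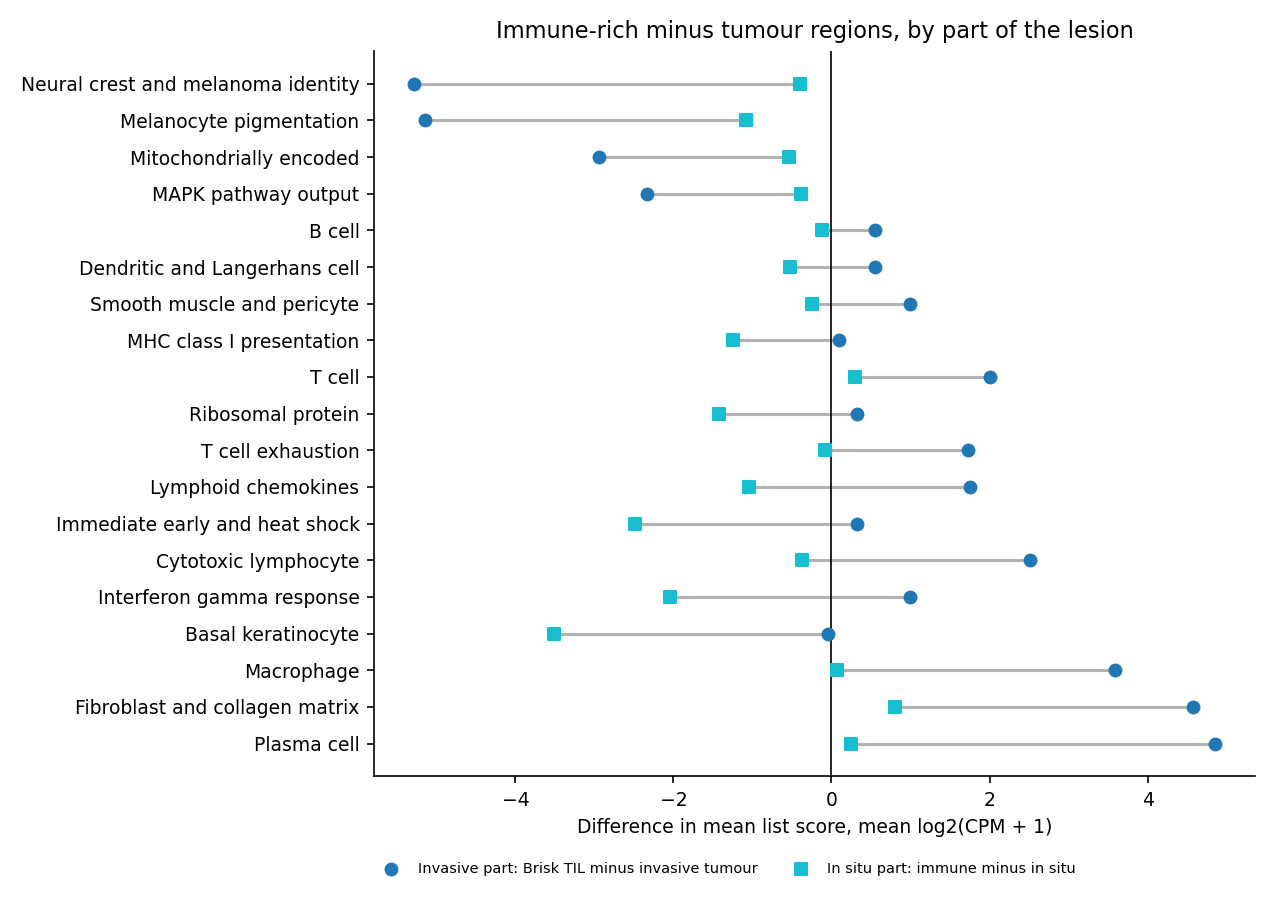
Difference in mean list score (log2(CPM + 1) scale) in the invasive part (circles, Brisk TIL minus invasive tumour) and the in situ part (squares, immune minus in situ). Shown are the 19 lists whose differences differed at an adjusted p under 0.05. The plasma cell list lies at 4.85 and 0.25, the basal keratinocyte list at -0.04 and -3.51. Scores cannot fall below 0, and basal keratinocyte scores reached at most 1.79 in invasive tumour. A difference of -3.51 was therefore not possible in the invasive part. By share of counts 11 lists passed. Fewer genes were detected in immune than in in situ regions, and a score falls when fewer of its genes are counted.

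Across the comparisons, 50 list calls were made with the preset correlation of 0.01 in camera, and 31 of them passed with an estimated correlation. These were all but the ribosomal list in Brisk TIL against tumour, both lists at the margin, and all but the macrophage, hypoxia and ribosomal lists in Brisk TIL against the margin. They were also all but the mitochondrial, oxidative phosphorylation and interferon gamma lists in situ against invasive tumour, the interferon gamma list of resolved regions, and 9 of 14 lists of the difference of differences. Each of the 31 had a larger adjusted p with the estimated than with the preset correlation. For pigmentation genes in Brisk TIL against the margin it was 3.54e-05 in place of 1.24e-08.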

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

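In this part the tests of thinned in situ depth and keratinocyte content, and the splits for the genes tested in both pairs of classes, were chosen before their results were seen, and the other tests only after.

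COL6A3 was the largest gene in 5 of 6 in situ, 9 of 14 immune and 5 of 16 invasive tumour regions, and 1 in situ region lay far below the other 5, at 36953 CPM or 3.70% of counts. Collagen-producing stroma would bring the partner chains COL6A1 and COL6A2, but in invasive tumour these summed to 0.0432% of the COL6A3 level, which argues against stroma as its source there. A fixed number of counts per library as its whole source is argued against, as the share would then fall with depth at a slope of -1, while within classes the log2 share fell with log2 depth at a slope of -0.43 (95% interval -0.553 to -0.314, Pearson r = -0.579, permutation p = 1.00e-05, Spearman rho = -0.546, permutation p = 1.00e-05, r = -0.527 without the 2 farthest regions, n = 72). A fixed amount that makes up part of the counts, or one set before amplification and sequencing, cannot be told apart from other sources, because total counts mix captured material with sequencing depth. The share also has the total as its denominator, which by itself pulls the slope below 0. Over the 4 relations computed the adjusted p was 4.00e-05 for both r and rho, while COL6A3 did not follow the other fibroblast genes (r = -0.0396, permutation p = 0.727, rho = -0.0243, permutation p = 0.836, r = -0.0845 without the 2 farthest, adjusted p = 0.801 and 0.836). The reads along the gene were not examined.

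Melanocyte transcripts were lower in in situ than in invasive tumour regions, and among the 6 in situ regions 1 lay far above the others for each of 4 genes, a different region for each: PMEL (497 CPM), TYR (33.1 CPM from 7 counts), MLANA (264 CPM) and QPCT (3.15 CPM from 1 count). Less sequencing of the in situ libraries is argued against: with invasive libraries thinned to in situ totals the pigmentation score averaged 5.53 against 1.91, and the largest permutation p over 20 draws was 2.68e-05. Thinning final counts does not imitate less RNA captured before amplification. That explanation was not tested and stays open. The choice among the 3 scalings is argued against by size, as TMMwsp and DESeq2 size factors moved the median log2 fold change of all genes by 0.82 and 0.28, while the pigmentation median went from -5.47 to no nearer 0 than -4.76. More keratinocytes among the captured cells cannot be told apart from fewer or less pigmented melanocytes, as 6 regions are too few: pigmentation and basal keratinocyte shares gave rho = -0.257 (exact p = 0.658, r = 0.142, exact p = 0.801, r = -0.883 without the 2 farthest, adjusted p = 0.836 and 0.801). A difference in pigmentation between confined and invasive tumour cells stays open and was not tested.

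By a test of the difference itself, immune minus in situ regions differed from Brisk TIL minus invasive tumour regions for 703 of 5799 genes. Of 100 splits of the same regions 1, the real one, gave as many, but the highest other gave 499 and the median other 275, so the test makes many calls on shuffled classes and the number itself says little. For the 394 genes tested in both pairs of classes, 17 were called, 1 of 100 splits gave as many, the real one included, and the highest other gave 5. These splits also remove the class differences within each part, so they do not test the difference of differences alone. They treat regions as independent, so chance is not excluded where regions share a person. With a block on region numbers present in at least 2 of the 4 classes 31 of all tested genes were called, and the same regions without the block gave 664. Region numbers are not said to pair regions, so this block does not test for shared persons. The median log2 difference of differences was 8.28 for pigmentation, 4.74 for neural crest, 3.16 for MAPK target and 1.96 for mitochondrially encoded genes. Pigmentation genes were already low in melanoma in situ, which left less room for a fall there. It was -8.05 for plasma cell, -4.76 for macrophage, -2.28 for cytotoxic lymphocyte and -3.41 for lymphoid chemokine genes. Fibroblast genes had -6.81, immediate early genes -2.96, basal keratinocyte genes -1.89, activated keratinocyte genes -0.96, interferon gamma genes -1.12 and ribosomal protein genes -0.98. The collagen gene COL1A2 was already at 1143 CPM in melanoma in situ, which left less room for a rise there. Keratinocyte and immediate early scores were already low in invasive tumour, which left less room for a fall in the invasive part.

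Of 79 sets of 6 or 8 region values examined for a region far from the others, 26 held one, where chance gives about 1 in 20 for normally distributed values. By kind these were 24 of 51 sets of gene levels, 2 of 12 of library measures and 0 of 16 of list scores on the log scale. The genes examined were those named in the text, some of them already seen to have most counts in 1 region. Their number cannot therefore be set against chance. Gene levels in CPM with many values at or near 0 are far from normal, so more than 1 in 20 of them can be reached without any unusual region. Beside those above, 1 in situ region stood highest for each of these genes, not the same region for all: C1S (339.9 CPM), COL1A1 (2785 CPM), FAM98C (10538 CPM), KLRD1 (15565 CPM), KRT15 (1051 CPM), MT-ND2 (11530 CPM), PERP (6534 CPM), PEX26 (8075 CPM), S100A8 (7297 CPM), SFRP1 (1517 CPM), SLC35A3 (13526 CPM), SYTL1 (10017 CPM), WARS1 (4813 CPM) and ZBTB25 (25882 CPM). One in situ region had 9.76% mitochondrial counts. Of the 8 resolved regions, 1 stood highest for each of 5 genes, again not the same one for all: B2M (144 CPM), FTH1 (1228 CPM), IRF1 (357 CPM), KRT6A (9588 CPM) and PSAP (1812 CPM).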

How the results depend on the processing

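For 251 named-gene results, the alternatives set beforehand gave 2182 values. Of these, 1936 stayed on the same side of the threshold, 107 newly passed, 136 no longer passed and 3 changed direction with at least 1 of the 2 values past the threshold. Of 724 values from alternatives added after the data were seen, 662 stayed, 2 newly passed and 60 no longer passed. A change of direction in which neither value passed is counted as staying. Genes that an alternative did not test, or gave no adjusted p, are left out. The 3 that changed direction were LEPROT, from -2.93 without EM replicate 1 to 8.15 without replicate 2, ZNF141, from -4.18 without EM replicate 2 to 7.56 without replicate 3, and CXCL11 in the difference of differences (0.62 with detected genes as covariate). Where not said otherwise, the cause of a changed count was not tested. With no filter on low counts, Brisk TIL against tumour gave 5619 genes in place of 88, the margin against tumour 4094 in place of 0, Brisk TIL against the margin 4835 in place of 53, exophytic 420 in place of 5, in situ against invasive 1697 in place of 171, immune against in situ 2679 in place of 0, resolved against immune 4769 in place of 0 and the difference of differences 2320 in place of 703. On the genes tested in both pairs of classes, which are fewer, the last gave 17. With at least 10 counts in 0.5 of the regions of a class the numbers were, in this order, 297, 26, 213, 45, 309, 72, 10 and 221, and 70 in place of 0 for resolved against in situ. DESeq2 gave 153, 11, 102, 186, 401 and 4 for the first 6, and 1 for resolved against in situ. It gave no adjusted p for 923 tested genes at the margin, 3402 for exophytic, 546 for in situ against invasive and 1823 for the difference of differences, and for at most 66 in each other comparison. limma voom gave 249, 15, 224, 56, 237, 6, 2 and 237 in the order of the first list, and 1 for resolved against in situ. Fisher's exact test gave 224 for Brisk TIL against tumour, 112 against the margin, 0 for exophytic (99 at an unadjusted p under 0.05) and 5 for in situ against invasive. For the latter, TMMwsp factors gave 55, DESeq2 size factors 65, all 75 regions in one fit 22, detected genes as covariate 62, the fit without COL6A3 and immunoglobulin counts 70 and the fit without mitochondrial counts 66. Without mitochondrial counts Brisk TIL against the margin gave 32, and all 75 regions in one fit gave 2 for exophytic regions, which ranged from 9 to 14 when 1 exophytic region was left out. The balance of directions turned in some of these. With no filter 1367 were higher and 330 lower for in situ against invasive, 2820 were higher and 2799 lower for Brisk TIL against tumour and 2477 were higher and 2358 lower against the margin, where most calls of the main analysis were lower. For exophytic regions 4 were higher and 182 lower with DESeq2, where all 5 of the main analysis were higher.

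Region numbers are not said to pair regions, and in the 5 comparisons of classes that share numbers none of the same-numbered pairs correlated above 0.0735; the best match had the same number in 3 of 16, 2 of 12, 0 of 12, 0 of 3, 0 of 6 cases. A replicate block on these numbers gave 161 genes in place of 88 for Brisk TIL against tumour, 3 in place of 0 for the margin, 3 in place of 5 for exophytic, 34 in place of 171 for in situ regions and 73 in place of 53 for Brisk TIL against the margin. The same regions without the block gave 88, 0, 5, 24 and 44, and of the 5 exophytic genes 0 were called with the block and 0 on those regions without it. For the difference of differences a block on the numbers present in at least 2 of the 4 classes, added after the data were seen, gave 31 in place of 703, 29 of them among the 703, and the same regions without the block gave 664, so the fall came with the block and not with the regions left out. Of its 14 list calls 11 held with the block and 13 without it. Immune and in situ regions share no numbers, so with this block their difference was reached only through Brisk TIL and invasive tumour regions. The fall in calls therefore says nothing about regions that share a person. No paired analysis was possible for the comparisons within the in situ part because these classes share no numbers.

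Of 50 list calls, 31 held with an estimated correlation, 50 with DESeq2 size factors, 48 with TMMwsp factors, 49 in one fit, 44 with the stricter filter, 47 with none, 42 with the covariate, 39 by permutation of scores and 34 of shares, and none changed direction. Without the region of very low depth, 20 of the calls were rerun and 17 held. The median log2 fold change of all genes moved with TMMwsp and DESeq2 factors by 0.82 and 0.28 for in situ against invasive, 0.21 and 0.10 for Brisk TIL against tumour, 0.28 and 0.22 against the margin, -0.14 and -0.05 for the margin, -0.11 and 0.07 for exophytic, 0.30 and 0.18 for immune, -0.40 and -0.37 for resolved against immune regions, and 0.11 and 0.14 for the difference of differences.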

Other observations

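In this part the test of melanocyte content was chosen before its result was seen, and all other tests, with the splits, only after.

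Genes of antigen presentation by MHC class I took 0.412% ± 0.154 of counts in melanoma in situ and 1.84% ± 0.551 in invasive tumour (adjusted p = 0.000174, exact permutation test). As a list they did not pass: camera gave adjusted p = 0.722 on 6 tested genes, of which 1 passed the test over all genes, as lower, and 2 had a log2 fold change above 0 without passing, and scores were 3.28 ± 0.74 against 3.56 ± 0.77 (adjusted p = 0.590). B2M, the light chain shared by all class I molecules, averaged 1139.9 ± 1197 CPM in situ, 359.9 ± 1059.6 CPM in immune and 18.4 ± 50.7 CPM in resolved regions. In the invasive part it averaged 15036 ± 5038 CPM in tumour, 17459 ± 6510.4 CPM at the margin and 10602 ± 4894 CPM in Brisk TIL. CD74 had 8063 ± 2808 CPM in Brisk TIL, 7359.6 ± 1786 CPM at the margin and 3107 ± 2531 CPM in tumour. Type I interferon genes took 0.111% ± 0.105 of counts in Brisk TIL and 0.266% ± 0.244 in tumour (adjusted p = 0.0126, permutation test), with IFI6 at 169 ± 402 and 749 ± 457 CPM, but passed neither by score (adjusted p = 0.0793) nor by camera (adjusted p = 0.140, 3 tested genes). The basal keratin KRT5 had 4259 ± 5899 CPM in immune and 7548 ± 8292 CPM in resolved in situ regions, and KRT6A, a keratin of activated epidermis with the near-identical paralogs KRT6B and KRT6C that make its count uncertain, 1635 ± 3622 and 2296 ± 3193 CPM. The order of the 2 KRT6A means turned without resolved region 24. These genes were chosen after their values were seen, and p-values over regions that share a person are too small. The Brisk TIL mean without its largest region was 72.8 CPM for IFI6 (region 1). The melanoma in situ mean without its largest region was 726 CPM for B2M (region 4). Immune in situ means without the largest region were 85.4 CPM for B2M (region 13) and 799.3 CPM for KRT6A (region 8). Resolved in situ means without the largest region were 0.494 CPM for B2M (region 26) and 1254 CPM for KRT6A (region 24).

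Mitochondrially encoded transcripts were lower in Brisk TIL than in invasive tumour regions. Antibody and COL6A3 counts taking up the share are argued against: without them the share was 2.21 ± 0.571% against 8.21 ± 2.56% (permutation p = 2.00e-05), 3.72 times lower, and 4.17 times with all counts. Shallower Brisk TIL libraries are argued against too, as the 10 with totals above the tumour median reached at most 2.65%, below the lowest tumour region at 3.98%. Fewer melanocytes among the captured cells may explain part of it: within tumour and margin regions the share rose with the pigmentation score (rho = 0.433, permutation p = 0.0237, adjusted p = 0.0474; r = 0.521, permutation p = 0.00502, adjusted p = 0.01004; r = 0.375 without the 2 farthest; n = 28). Other differences between lymphocytes and tumour cells were not tested.

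In 3 comparisons no other split drawn reached the number of genes called in the main fit. The splits treat regions as independent, so they cannot account for regions that share a person. Of 100 splits of the same regions, 1, the real one, gave at least 88 genes for Brisk TIL against invasive tumour (highest other 1), 1 gave at least 53 for Brisk TIL against the margin (highest other 1) and 1 gave at least 171 for in situ against invasive tumour (highest other 9). Chance is not excluded for the 5 genes of exophytic against invasive tumour, which 49 of 100 splits reached (highest other 13). For the 4 comparisons in which edgeR called 0 genes the splits carry no information, as each of the 100 gives at least 0 genes whatever the data. The highest other was 1 for the margin, 2 for immune against in situ, 1 for resolved against in situ and 3 for resolved against immune regions.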
